A study of Mus musculus with 12 samples.

How the data were processed

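Whole kidneys of db/m and db/db mice were compared at 8 and 16 weeks of age. The db/db mouse is homozygous for a mutation of the leptin receptor gene Lepr and becomes obese and diabetic, and db/m mice carry 1 mutated copy and served as the lean control. Total RNA was extracted with RNeasy columns, and labelled target was made from about 8 ug of it by standard Affymetrix procedures. Each of the 4 groups held 3 arrays, which the labels call biological replicates, so 12 arrays were analysed. A keyword in the sample descriptions reads db/m on every sample, including those titled db/db. Groups were taken from the titles. Lepr itself could not check the genotypes, since none of its 2 probe sets was above the detection filter described here.

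The values deposited by the authors are intensity values on a linear scale, 1 per probe set, for 12488 probe sets of a mouse expression array. The authors had multiplied each array by a single factor: the mean without the highest and lowest 2% of probe sets was about 1501 on every array. Software and version were not given in the sources used here, and neither were detection calls. The number of arrays, not a read depth, limits the precision of array data. Median intensity was 412 to 442 on the db/m arrays and 498 to 555 on the db/db arrays.

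The 66 control probe sets were left out of the comparisons and used as checks of array quality. The remaining values were quantile normalised between the 12 arrays. Values under the 30th percentile of the normalised distribution, an intensity of 155, were raised to it, and the logarithm to base 2 was taken. A probe set was kept if it was above the 50th percentile, an intensity of 474, on at least 3 of the 12 arrays, which left 6954 probe sets. These covered 5361 genes, of which 821 had at least 2 kept probe sets. The array annotation gave 1 gene symbol for 10833 probe sets, several for 396 and none for 1193. The mouse gene table of the GRCm38.p6 assembly served only to bring symbols up to date and to find neighbours of Lepr, and no position is reported because no genome build was used to make the values. Where all arrays of a group were at the floor, a fold is given as a lower bound. Mean intensities are geometric means of the normalised values.

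A model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, which left 8 residual degrees of freedom and added 3.33 prior degrees of freedom. From it came 6 comparisons: db/db with db/m at 8 weeks, at 16 weeks and averaged over both ages, the difference between the genotype effects at the 2 ages (the interaction), and 16 with 8 weeks within each genotype. Tests were two-sided. Adjusted p refers to the Benjamini-Hochberg adjustment of limma's moderated test over all kept probe sets, with a threshold of 0.05, and passed, rose and fell refer to it. A probe set was called separated where the 3 values of one group all lay above the 3 of the other. Replicate numbers did not pair the samples: of 18 pairs of arrays with the same number in different groups, 1 had a correlation over 0.1 after group means were removed, and the mean correlation was -0.047.

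The 38 gene lists with 1201 symbols were fixed before the data were examined, as were the comparisons, filters, most alternatives and the rule for named genes. Of the symbols, 1196 matched a gene. The lists covered metabolic pathways, injury, immunity, hormones, the nephron's cell types and tissues that adjoin the kidney. With a minimum of 5 kept members, 37 lists were tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01. The list of sex chromosome genes had 1 kept member and was not tested. Camera was repeated with a correlation estimated from the residuals, and fry, which tests a list by itself, was run beside it. A list's adjusted p is over the 37 lists. Counts of members refer to all probe sets tested, and counts adjusted over the list alone are given beside them. A gene was represented by its probe set with the highest mean.

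The genes named were chosen by the rule, not by interest. For 8 and for 16 weeks they are the 10 higher and the 10 lower genes with the largest change among those past the threshold and separated. The other comparisons take up to 5 in each direction, and each list up to 4 members that passed in any comparison. A panel of 27 genes was fixed as well: 20 had a probe set, 16 were kept, and 7 had none. Not all members that the rule allows are printed for each list, so those printed can lean to one direction.

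Alternatives changed the scaling between arrays (values as deposited, or a common median), the floor, the filter, the variance model, array weights, the arrays in the fit, the probe set per gene and the replicate block, and left out each array in turn. An array left out leaves 2 in its group, and limma's pooled spread serves all groups. Chosen after seeing the data were a covariate made from the 3' to 5' ratios of the actin and pyruvate carboxylase control probe sets, the omission of 2 db/db 16 week arrays that stood apart, the omission of the 2 db/m 16 week arrays with the highest Acta1, and the omission of probe sets prone to cross-hybridise. Relative to quantile normalisation, scaling moved the median of all genes: the median log2 difference of db/db and db/m was -0.01 at 8 weeks and -0.03 at 16 weeks, became 0.1 and 0.05 on values as deposited, and became -0.25 and -0.21 with a common median.

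The model fit and threshold were tested on simulated data, with changes added to 200 of the 6954 probe sets. The noise was normal, independent between probe sets and of equal spread in all groups, unlike the real arrays. It was added to means already normalised and filtered, so scaling, floor and filter were not tested. Each comparison had 1 such run, with far fewer changes than were called between the genotypes. For the 8 week comparison, 23.9% of 1.5-fold, 61.2% of 2-fold and 90.9% of 4-fold changes were recovered, and 4.1% of the calls were false. For the interaction these were 1.49%, 26.9%, 74.2% and 1.45%. For age in db/m kidneys they were 17.9%, 55.2%, 95.5% and 10.4%. That share of false calls lay above 0.05, though 1 run cannot tell if this holds in general. In the other 3 comparisons 2.59% to 4.43% of the calls were false. Figures were drawn with matplotlib 3.10.9. Raw image files were not used here.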

Results

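Whole kidneys of db/m and db/db mice were compared at 8 and 16 weeks (3 arrays per group). Arrays of the same group correlated with each other at 0.895 to 0.971 and arrays of different groups at 0.812 to 0.964. The first principal component held 45.9% of the variance and put all db/m arrays on one side of all db/db arrays, and the second held 18.2%. At 16 weeks, db/db replicate 1 lay apart from replicates 2 and 3: its score on the first component was 15.2 against 47.2 and 49.7, and its correlations with them were 0.924 and 0.895 against 0.958 between them. Control probe sets differed as well. The ratio of 3' to 5' signal of actin was 1.41 in db/db and 2.06 in db/m arrays (geometric means, 6 arrays each).

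**Figure D1:**
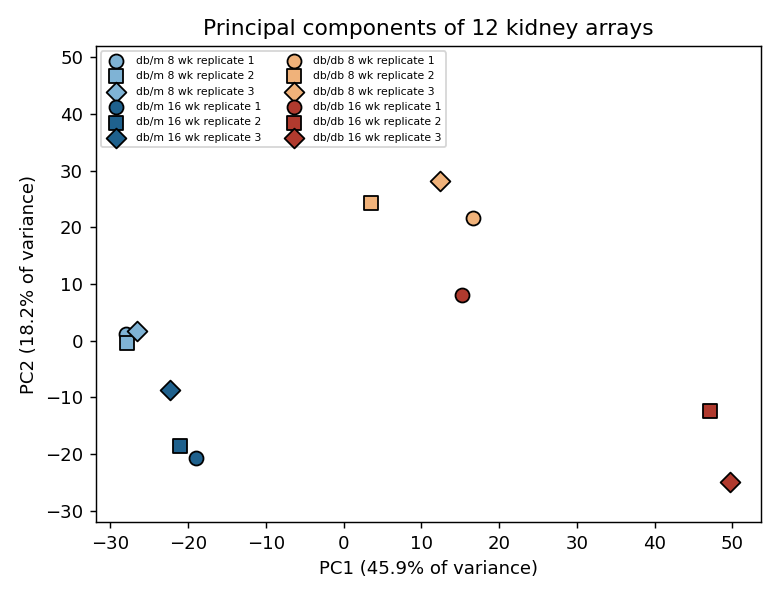
Scores of the 12 arrays on the first 2 principal components of the normalised log2 intensities, with colour for the group and shape for the replicate. The db/m arrays lie at negative scores of the first component, and db/db 16 week replicate 1 lies at 15.2, apart from replicates 2 and 3.

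The comparison at 8 weeks asks how the kidney of the db/db mouse differs early. Kidneys of db/db mice held far more mRNA for Bhmt, which passes methyl groups from betaine to homocysteine, and for Gsta2, a glutathione transferase. Mean intensity of Bhmt (94049_at) was 213 in db/m and 4026 in db/db kidneys (log2 fold change 4.24, SE 0.48, adjusted p from limma 0.000525), and that of Gsta2 (101872_at) was 2272 and 24440 (3.43, SE 0.29, adjusted p from limma 0.000184). Far lower in db/db kidneys were Cyp7b1, an oxysterol hydroxylase under androgen control in the mouse kidney, and Idi1, an isomerase of cholesterol synthesis. Cyp7b1 (92898_at) fell from 7868 to 504 (-3.96, SE 0.44, adjusted p from limma 0.000525) and Idi1 (96269_at) from 8542 to 867 (-3.3, SE 0.35, adjusted p from limma 0.000404). On all 3 db/db arrays these 4 genes lay beyond every db/m array.

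Enzymes that make and degrade active vitamin D both rose at 8 weeks. Cyp27b1, which makes it, rose by 3.36 (SE 0.7) on the log2 scale and Cyp24a1, which degrades it, by 2.66 (SE 0.76). Other genes with the largest rises were Cyp4a14, a fatty acid omega-hydroxylase (2.67), the dynein light chain Dynll2 (2.39), the disulfide isomerase P4hb (2.19), the class I-like molecule H2-M9 (2.16), the RNA-binding protein Hnrnpl (2.15) and Foxm1, a transcription factor of dividing cells (2.15). Among the largest falls were the nucleoporin Nup54 (-2.84), the monooxygenase Fmo5 (-2.75), the lipoxygenase Alox15 (-2.52), Abcf2 (-2.47), the phosphatase Ptpn22 (-2.44), the metalloprotease Adam28 (-2.43), the dipeptidase Cndp2 (-2.41) and the tumour suppressor Men1 (-2.38). The call of Cyp24a1 ended without single arrays, at adjusted p 0.105, 0.0619 and 0.0588 without db/m 8 week replicates 1, 2 and 3, and 0.0839 and 0.102 without db/db 8 week replicates 2 and 3 (0.00579 to 0.135 over all its alternatives). That of Adam28 ended without the same arrays, at 0.0638, 0.0907, 0.0736, 0.0768 and 0.0985 (0.00134 to 0.519 over all its alternatives).

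Androgen-responsive and sex-dimorphic kidney genes were lower as a group in 8 week db/db kidneys: 9 of 15 fell and 1 rose, and 10 and 1 when adjusted over the list alone (camera, adjusted p = 0.000434). With an estimated correlation the adjusted p was 0.682, the highest of its alternatives, and the lowest was 1.7e-05. Beside Cyp7b1, the ornithine decarboxylase gene Odc1 fell by 1.64 (SE 0.23) and the alcohol dehydrogenase gene Adh1 by 1.63 (SE 0.18) on the log2 scale. Of 18 glucocorticoid-responsive genes 6 rose, and 10 did when adjusted over the list alone (camera, adjusted p = 0.000153, and adjusted p = 0.626 with an estimated correlation, 1.66e-05 to 0.626 over its alternatives). The transcription factor Zbtb16 rose by 1.81 (SE 0.42), while Angptl4 and Pdk4, at 0.62 and 0.54, did not pass.

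Of 14 genes of cholesterol synthesis and uptake 4 fell at 8 weeks, and 6 fell and 1 rose when adjusted over the list alone. The lanosterol demethylase Cyp51 fell by 1.99 (SE 0.16) on the log2 scale. The list passed with camera (adjusted p = 0.0312), with adjusted p = 0.626 with an estimated correlation and 0.0551 without db/m 8 week replicate 1 (0.00237 to 0.626 over its alternatives). It did not pass at 16 weeks, where 5 fell and 2 rose, 6 and 3 adjusted over the list alone (adjusted p = 0.259), or in the average of both ages, where 7 fell and 2 rose, also adjusted over the list alone (0.0951).

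Of 34 genes of glutathione and antioxidant defence 10 rose and 5 fell at 8 weeks, and 13 and 6 did when adjusted over the list alone (camera, adjusted p = 0.0428, and adjusted p = 0.626 with an estimated correlation). The list's mean was 0.38, 0.31 on values as deposited, and turned to -0.02 with a common median. Gsta2 and the metallothionein gene Mt1 (1.19, SE 0.26) were among the genes that rose, though the call of Mt1 ended with a common median (adjusted p 0.129, 0.000846 to 0.129 over its alternatives). The list's call ended on values as deposited (adjusted p 0.631), without db/m 8 week replicates 2 and 3 (0.059 and 0.0512), without db/m 16 week replicate 2 (0.0524) and without db/db 8 week replicate 2 (0.0791), with a range of 0.00291 to 0.631 over all alternatives.

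Of 22 genes of tubular injury and repair 3 rose at 8 weeks, also when adjusted over the list alone (camera, adjusted p = 0.0247, and adjusted p = 0.693 with an estimated correlation), while Cdkn1a, the cell cycle inhibitor p21, at 1.25 and Egr1 at 0.67 did not pass. That call ended with fry (0.177) and without the filter (0.0633), with a range of 0.00309 to 0.693. Of 16 immediate early genes, which respond within minutes to stimuli that include dissection, 2 rose, and 1 did when adjusted over the list alone (adjusted p = 0.0435, and adjusted p = 0.729 with an estimated correlation). This call ended with fry (0.293) and without db/m 8 week replicates 1 and 3 (0.0537 and 0.0657), db/m 16 week replicate 2 (0.0524) and db/db 8 week replicate 2 (0.0791), with a range of 0.00309 to 0.729 over all alternatives.

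Several single genes of known function in the diabetic kidney differed at 8 weeks. Igf1, insulin-like growth factor 1, rose by 1.54 (SE 0.22) on the log2 scale and its binding protein Igfbp1 by 1.46. The growth factor list to which both belong went the other way, with means of -0.23, -0.11 and -0.22 over the 8 week db/m mean on db/db replicates 1, 2 and 3. Ace, the angiotensin-converting enzyme, fell by 1.56 (SE 0.18), and Hsd11b1, which regenerates active glucocorticoid, by 1.93. The fatty acid transporter Cd36 fell by 1.66, and Pck1, a rate-limiting enzyme of gluconeogenesis, rose by 0.88, a call that ended with a common median (adjusted p 0.132, 0.00135 to 0.142 over its alternatives). The peptide transporter Slc15a2 fell by 1.24 (SE 0.15) and the brush border protease Mep1b by 1.65, whereas the lactate transporter Slc16a1 rose by 1.39. Calb1, calbindin of the distal tubule, rose by 1.37.

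In the comparison at 8 weeks, 1324 of 6954 probe sets passed: 593 were higher and 731 lower in db/db kidneys, and 233 and 252 of these by at least 2-fold. They represented 1035 genes. Groups were separated for 3210 probe sets, or 46.2%, where chance gives 10%. The split between higher and lower depended on scaling, with 1075 higher and 616 lower on values as deposited and 409 and 1757 with a common median, and 2355 passed with array weights and 131 with the 3' to 5' ratio as a covariate. Without single arrays the count moved by over 1.5 times in 5 cases: it was 775, 796 and 782 without db/m 8 week replicates 1, 2 and 3, and 707 and 659 without db/db 8 week replicates 1 and 3. With the covariate, the calls of Bhmt, Gsta2, Cyp4a14, Cyp7b1, Idi1, Nup54, Fmo5, Alox15, Cndp2, Men1, Cyp51, Adh1, Igf1, Ace, Hsd11b1, Cd36 and Slc15a2 held and those of the other genes named for 8 weeks ended.

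**Figure D2:**
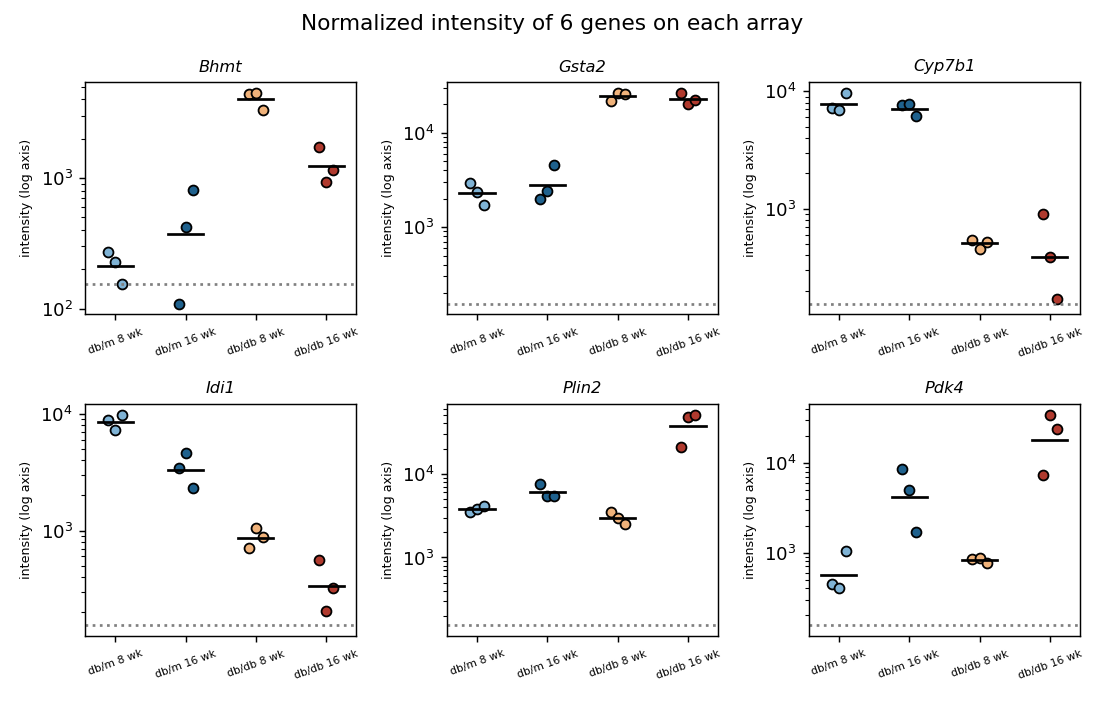
Normalised intensities of 6 genes on a log axis, with a point per array, a line at each group's geometric mean (3 arrays) and the floor of 155 dotted. Gsta2 lies higher and Cyp7b1 and Idi1 lower on every db/db array, and Plin2 is highest in the 16 week db/db group, at a mean of 36870.

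The comparison at 16 weeks asks how the kidney differs once diabetes has lasted longer. In db/db kidneys Plin2, which coats lipid droplets, rose from 6013 to 36870 (98589_at, log2 fold change 2.62, SE 0.3, adjusted p from limma 0.000275). Gsta2 was again far higher (2780 and 22890, 3.04, SE 0.29, adjusted p from limma 0.000167). Again far lower were Cyp7b1 (-4.2, SE 0.44, adjusted p from limma 0.000231), Idi1 (-3.31, SE 0.35, adjusted p from limma 0.000231) and Cyp51 (94916_at), which fell from 1773 to 279 (-2.67, SE 0.16, adjusted p from limma 1.35e-05). All 3 db/db arrays lay beyond all 3 db/m arrays for these 5 genes.

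Beside Gsta2 and Plin2, 8 genes had the largest rises at 16 weeks by the probe set that represents each gene. Ddit4, an inhibitor of mTOR signalling induced by stress and glucocorticoids, rose by 3.25 (SE 0.53), the epithelial keratin Krt20 by 3.17 (SE 0.75), Cdkn1a by 3.12 (SE 0.57) and the tight junction protein Cldn4 by 2.88 on the log2 scale. The serine protease Prss30 rose by 2.69 and Lrg1, a secreted glycoprotein of the acute phase, by 2.67. Vax1, a homeobox gene, and the sialyltransferase St3gal3 were at the floor on all db/m arrays, and were at least 6.24-fold and at least 6.02-fold higher. The calls of Krt20 and Cdkn1a ended without db/db replicates 2 and 3, a fit that leaves 1 array in the group. Both genes belong to the injury list, whose mean over the 8 week db/m mean was 0.55 on replicate 1 and 1.7 and 1.67 on replicates 2 and 3. Over all alternatives the adjusted p ranged from 7.71e-05 to 0.442 for Krt20 and from 1.95e-05 to 0.225 for Cdkn1a.

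Among the genes lower at 16 weeks, Acta1, the actin of skeletal muscle, was at the floor on all db/db arrays and at least 20.2-fold lower, and the muscle myosin light chain Myl1 fell by 2.67 (SE 0.68). The db/m arrays differed in these muscle transcripts, with Acta1 at 2620, 7479 and 1564 on db/m 16 week replicates 1, 2 and 3. Pzp, a protease inhibitor, fell by 3.42 (SE 0.5), and Alox15 fell by 2.9, the histone gene H3c14 by 2.83, Nup54 by 2.74 and the phosphatase subunit Ppp2r5d by 2.72. Of 8 skeletal muscle genes 4 fell at 16 weeks, and 4 fell and 1 rose when adjusted over the list alone (camera, adjusted p = 0.243, not passed).

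Androgen-responsive and sex-dimorphic genes were lower again: 11 of 15 fell, also when adjusted over the list alone (camera, adjusted p = 7.41e-05, and adjusted p = 0.466 with an estimated correlation, 2.99e-06 to 0.466 over its alternatives). Odc1 fell by 1.87, Timd2, a ferritin receptor, by 1.85 and Adh1 by 1.71. Of 21 markers of proximal tubule cells, which border on this group, 9 fell and 1 rose, the same counts as when adjusted over the list alone (camera, adjusted p = 0.0448, and adjusted p = 0.406 with an estimated correlation). The brush border protease Mep1b fell by 2.64 (SE 0.34) and Keg1, a glycine acyltransferase, by 1.76. This call ended without single arrays: db/m 16 week replicates 1 and 3 (0.0714 and 0.0676), db/db 8 week replicates 1, 2 and 3 (0.0516, 0.0582 and 0.0572) and db/db 16 week replicates 1, 2 and 3 (0.0524, 0.057 and 0.0604), with a range of 0.000278 to 0.406. Of 25 genes of proximal tubule transport 9 fell and 1 rose (10 and 1 adjusted over the list alone), which did not pass as a list (adjusted p = 0.243). Slc15a2 fell by 1.9 (SE 0.15), and Slc16a1 rose by 1.26.

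Glucocorticoid-responsive genes rose as a group at 16 weeks, with 13 of 18 higher and 1 lower, and 14 and 1 when adjusted over the list alone (camera, adjusted p = 4.21e-05, and adjusted p = 0.366 with an estimated correlation, 9.45e-07 to 0.366 over its alternatives). Over the 8 week db/m mean the list stood at 1.63, 2.51 and 2.42 on db/db replicates 1, 2 and 3 and at 1.17, 0.99 and 0.76 on the db/m arrays, with replicate 1 nearer to db/m than replicates 2 and 3 were. Without replicates 2 and 3 the list still passed (0.00624). Zbtb16 rose by 2 (SE 0.42). Of 15 genes of the circadian clock 6 rose, also when adjusted over the list alone (camera, adjusted p = 0.0041, and adjusted p = 0.237 with an estimated correlation, 0.000409 to 0.237 over its alternatives). Wee1, Per1 and Bhlhe40 rose by 1.42, 1.36 and 1.16 on the log2 scale. Hours of tissue collection were not given in the sources used here.

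Immediate early genes rose in 11 of 16 cases and genes of tubular injury and repair in 10 of 22, the same counts as when adjusted over each list alone (camera, adjusted p = 4.21e-05 and 7.41e-05). With an estimated correlation both had adjusted p = 0.466. The transcription factors Junb and Ier2 rose by 2.55 (SE 0.5) and 2.04, and Krt20 and Cdkn1a belong to the injury list. These 2 lists followed db/db replicates 2 and 3: the mean of the immediate early genes was 0.74, 2.07 and 2.45 above the 8 week db/m mean on replicates 1, 2 and 3, and that of the injury genes 0.55, 1.7 and 1.67. Without replicates 2 and 3 the calls ended at adjusted p 0.284 and 0.223, with ranges of 2.52e-08 to 0.466 and 1.33e-07 to 0.466 over all alternatives.

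Of 34 genes of glutathione and antioxidant defence 9 rose and 4 fell at 16 weeks, also when adjusted over the list alone (camera, adjusted p = 0.0224, and adjusted p = 0.366 with an estimated correlation). Mt1 rose by 1.9 (SE 0.26) and Mt2 by 2.12 (SE 0.36). The call ended on values as deposited (adjusted p 0.142, 0.000805 to 0.366 over its alternatives). Of 29 genes of fatty acid beta-oxidation and ketogenesis 6 rose and 2 fell, and 6 and 1 did when adjusted over the list alone (camera, adjusted p = 0.0226, and adjusted p = 0.466 with an estimated correlation). That call ended on values as deposited (0.182), without db/m 16 week replicate 2 (0.0715) and without db/db 16 week replicate 1 (0.0516), with a range of 0.00561 to 0.466 over all alternatives.

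Of 18 genes of TGF-beta and BMP signalling 5 rose and 1 fell at 16 weeks, also when adjusted over the list alone (camera, adjusted p = 0.0448, and adjusted p = 0.406 with an estimated correlation). Id1, a target of BMP signals, rose by 1.21 and Bmp6 by 0.88. The call ended without db/m 16 week replicates 1 and 3 (0.0714 and 0.0663), db/db 8 week replicates 1 and 3 (0.0516 and 0.0572) and db/db 16 week replicate 2 (0.151), with a range of 0.0102 to 0.406. Of 6 markers of liver and pancreas, tissues that adjoin the kidney, 3 rose, also when adjusted over the list alone (camera, adjusted p = 0.0448, and adjusted p = 0.466 with an estimated correlation). Albumin, Alb, was at 364 in db/m and 818 in db/db kidneys, and its call ended without db/m 16 week replicate 1 and db/db 16 week replicate 2 (0.0775 and 0.0698, 0.000809 to 0.256 over its alternatives). This call ended without db/m 16 week replicates 1 and 2 (0.0845 and 0.0606), db/db 8 week replicate 3 (0.0572) and db/db 16 week replicates 2 and 3 (0.0771 and 0.102), with a range of 0.0242 to 0.466.

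Lists of matrix and inflammation did not pass at 16 weeks with camera or fry. Of 36 genes of extracellular matrix and fibrosis 5 rose and 6 fell at 16 weeks, and 4 and 5 did when adjusted over the list alone (adjusted p = 0.649). Among the laminin chains, which build basement membrane, Lamc1 rose by 1.54 and Lama5 by 0.83, and Lama3 fell by 2.15. Of 17 leukocyte markers 2 fell, also when adjusted over the list alone (adjusted p = 0.94), among them the macrophage receptors Csf1r (-1.1) and Fcgr2b (-1.52). Their mean was -0.66, 0.09 and 0.75 over the 8 week db/m mean on db/db replicates 1, 2 and 3, and without replicates 2 and 3 the list turned to lower and passed (adjusted p 0.00624, 0.00624 to 0.99 over its alternatives). Adjusted p was 0.585 for 17 genes of antigen presentation, 0.69 for 13 interferon-response genes, 0.585 for 10 chemokines, cytokines and adhesion molecules, and 0.249 for 16 genes of complement, acute phase and coagulation. Of that last list Serpina3n, an acute phase inhibitor, rose by 2.49 (SE 0.49) and the fibrinogen chain Fgg by 1.51.

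Of the 27 panel genes 16 had a kept probe set. Pck1 rose by 0.79 and Ace, Cd36 and Cyp2e1 fell by 1.01, 1.04 and 0.68 at 16 weeks, where the call of Cd36 ended without db/m 16 week replicate 2 (adjusted p 0.0517, 0.0112 to 0.218 over its alternatives). At 8 weeks Cyp2e1, a cytochrome P450 of ethanol and ketone metabolism, fell by 0.57, a call that ended without db/m 8 week replicates 2 and 3 (adjusted p 0.0523 and 0.0627) and without db/db 8 week replicate 3 (0.0725), with a range of 0.000782 to 0.11. The glucose transporter Slc2a2 stood at 0.5 at 8 weeks and fell by 0.99 at 16 weeks (adjusted p 0.0491). That call ended without every array other than db/db 16 week replicate 1, at 0.0557 to 0.173, and the value was 0.07 without db/db 16 week replicates 2 and 3, with a range of 0.000132 to 0.875 in adjusted p. Lcn2, a marker of tubular injury, was at 18430 and 17280 on db/db 16 week replicates 2 and 3 and at 588 on replicate 1 by one probe set (log2 fold change 4.2, SE 1, adjusted p from limma 0.00939), while the probe set that represents the gene gave 0.26 and did not pass. Values of Umod, Aqp2, G6pc, Cpt1a, Scd1, Fasn, Fn1, Col4a1, Ccn2 and Kap at 16 weeks were -0.24, 0.71, -0.42, -0.02, -0.23, -0.03, -0.11, 0.34, 0.05 and -0.22, none past the threshold.

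In the comparison at 16 weeks, 2357 probe sets passed: 1033 were higher and 1324 lower in db/db kidneys, and 406 and 538 of these by at least 2-fold. They represented 1831 genes. The split was 1359 higher and 1152 lower on values as deposited and 732 and 1995 with a common median. Groups were separated for 2978 probe sets, or 42.8%, where chance gives 10%. The count was 1451 without db/db 16 week replicate 2, 809 without replicates 2 and 3, 444 without the 2 db/m arrays with the highest Acta1, 1318 with the arrays of this age alone, 3745 with array weights and 2 with the 3' to 5' covariate, under which no gene named for 16 weeks passed. Without those 2 db/m arrays the calls of Ddit4, Krt20, Cdkn1a, Pzp and Myl1 ended at adjusted p 0.0645, 0.118, 0.0716, 0.0517 and 0.166, where the highest over all alternatives were 0.179, 0.442, 0.225, 0.129 and 0.475 and the lowest 4.19e-06, 7.71e-05, 1.95e-05, 1.08e-05 and 0.00423.

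**Figure D3:**
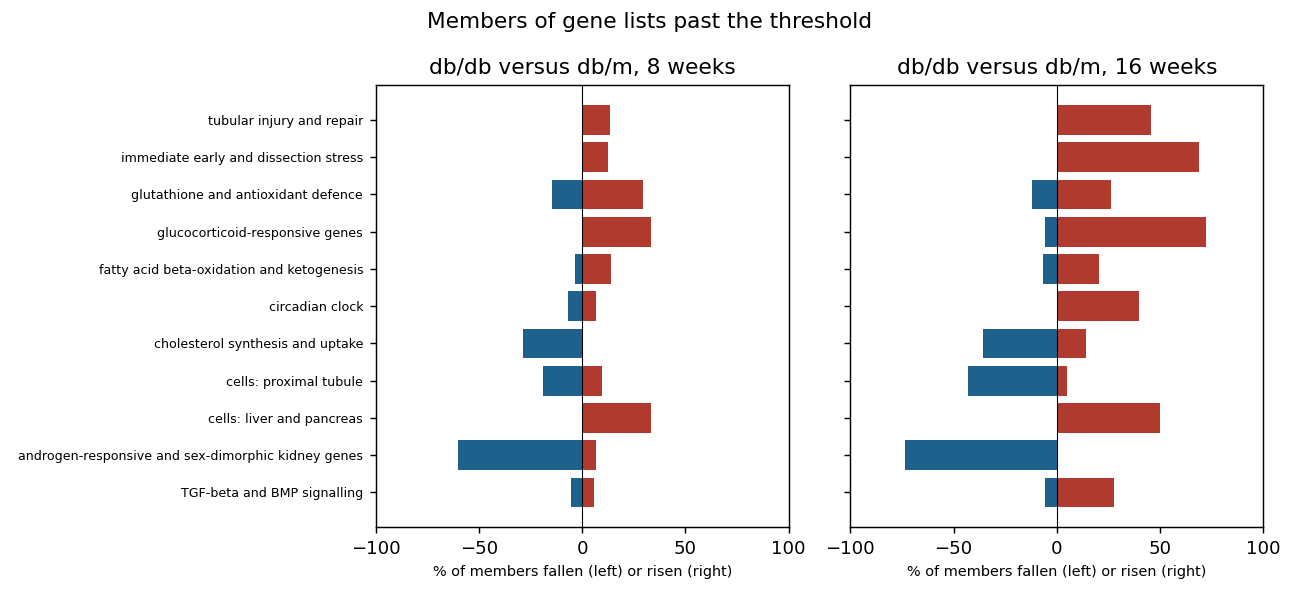
Percent of the kept members of 11 gene lists that fell (left of 0) or rose (right of 0) in db/db relative to db/m kidneys past the threshold, at 8 and 16 weeks. At 16 weeks 11 of 15 androgen-responsive genes fell and 13 of 18 glucocorticoid-responsive genes rose.

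Genotype effects at the 2 ages resembled each other. Of the probe sets that passed, 836 passed at both ages and 829 of these had the same sign: 349 were higher at both ages, where 88.1 would be shared by chance, and 480 were lower, where 139 would be. Across probe sets, which are not independent, the effects correlated at r = 0.662. Averaged over both ages, 3140 probe sets passed, 1470 higher and 1670 lower (1973 and 1397 on values as deposited, 1029 and 2753 with a common median), and the largest changes were those of Gsta2 (3.23, SE 0.2), Bhmt (2.97, SE 0.34), Prss30 (2.41), Cdkn1a (2.19), Ddit4 (2.18), Cyp7b1 (-4.08, SE 0.31), Idi1 (-3.31, SE 0.25), Nup54 (-2.79), Alox15 (-2.71) and Pzp (-2.57). With the 3' to 5' covariate 25 passed, with Cyp7b1, Nup54, Gsta2, Prss30, Fmo5, Cyp51, Adh1 and Slc15a2 among them, and without the 2 db/m arrays with the highest Acta1 2033 did.

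Of the lists, 8 passed for the averaged effect. Those of androgen-responsive genes (11 of 15 fell, 1 rose, and 12 and 1 adjusted over the list alone), injury (11 of 22 rose, also adjusted over the list alone) and immediate early genes (12 of 16 rose, also adjusted over the list alone) each had adjusted p = 0.000184, and adjusted p = 0.483 with an estimated correlation, the highest of their alternatives. Glucocorticoid-responsive genes rose in 14 of 18 cases, 15 adjusted over the list alone (adjusted p = 1.13e-05, and adjusted p = 0.291 with an estimated correlation). Glutathione genes rose in 13 and fell in 6 of 34 cases, 17 and 6 adjusted over the list alone (adjusted p = 0.0146, adjusted p = 0.291 with an estimated correlation, 0.321 on values as deposited, and 0.000127 to 0.321 over its alternatives). Clock genes rose in 6 of 15 cases, also adjusted over the list alone (adjusted p = 0.0291, and adjusted p = 0.291 with an estimated correlation). Beta-oxidation genes rose in 11 and fell in 2 of 29 cases, also adjusted over the list alone (adjusted p = 0.0201, adjusted p = 0.483 with an estimated correlation, 0.401 on values as deposited, and 0.0047 to 0.483 over its alternatives), and their mean of 0.31 turned to -0.03 with a common median. Liver and pancreas markers rose in 3 of 6 cases, also adjusted over the list alone (adjusted p = 0.0394, and adjusted p = 0.483 with an estimated correlation). That call ended at 0.0523 without db/m 8 week replicate 3, 0.0546 without db/m 16 week replicate 1, 0.052 without db/db 8 week replicate 3 and 0.0637 without db/db 16 week replicate 3, with a range of 0.00676 to 0.483.

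Fry, which asks whether a list moved by itself rather than more than other genes, called 6, 16 and 17 lists at 8 weeks, at 16 weeks and averaged, where camera called 6, 10 and 8. Those called by fry alone for the averaged effect were growth factors (adjusted p = 6.96e-05), cholesterol (0.000127), proximal tubule markers (0.000128), heat shock and unfolded protein response (0.0047), proximal tubule transport (0.021) and skeletal muscle (0.021), all lower, and TGF-beta and BMP signalling (0.0047), adrenal gland (0.0211) and cell cycle (0.0395), all higher. At 16 weeks they were growth factors (0.000278), heat shock (0.000818), cholesterol (0.00113), skeletal muscle (0.0116) and proximal tubule transport (0.0119), lower, and cell cycle (0.0251), higher, and at 8 weeks growth factors (0.00217) and proximal tubule markers (0.0486), lower.

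Other metabolic lists than beta-oxidation and glutathione did not pass with camera in the averaged effect, though single enzymes passed. For this effect 3140 of all 6954 probe sets passed, so members past the threshold do not by themselves mark a pathway. In gluconeogenesis 4 of 14 genes rose and 2 fell (adjusted p = 0.413), with Pck1 at 0.83, the transaminase Got2 at 1.05 and Ppargc1a at -0.98. In glycolysis and the pentose phosphate pathway 3 of 20 rose and 1 fell (0.425), with the transketolase Tkt at 1.08 and the phosphofructokinase Pfkp at -1.04. In the citric acid cycle 4 of 22 rose, 3 adjusted over the list alone (0.27), with the malate dehydrogenase Mdh1 at 0.73. Of 53 respiratory chain genes 7 rose and 9 fell, 6 and 8 adjusted over the list alone (0.802), with Atp5pb at 1 and Ndufc1 at -0.52. Of 21 genes of fatty acid and triglyceride synthesis 6 rose and 5 fell (0.625), with Plin2 at 1.13, Lpin1 at 0.78 and the lipoprotein lipase Lpl at -1.4. Of 34 genes of amino acid and urea metabolism 7 rose and 9 fell (0.739), with the branched-chain transaminase Bcat1 at -1.8.

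Lists of drug, hormone and protein handling and of division did not pass with camera in the averaged effect either. Their counts of members stand beside the same 3140 of 6954 probe sets. Of 19 cytochrome P450, glucuronosyltransferase and sulfotransferase genes 6 rose and 6 fell, 7 and 7 adjusted over the list alone (adjusted p = 0.897), and the monooxygenase Fmo5 was at -2.5. In the renin-angiotensin and vasoactive systems 5 of 14 rose and 5 fell, 5 and 7 adjusted over the list alone (0.958), with Ace at -1.28 and Hsd11b1 at -1.45. Of 23 growth factor genes of the diabetic kidney 3 rose and 10 fell, 3 and 11 adjusted over the list alone (0.376), with Igf1 at 1.27. In heat shock and the unfolded protein response 5 of 25 rose and 10 fell (0.625), with the chaperones Pdia3 at 1.27, Dnajb9 at 1.44 and Hspb8 at 1.31 among those that rose. Of 21 cell cycle genes 5 rose and 2 fell, 4 and 2 adjusted over the list alone (0.376), with the mitotic kinase Plk1 at 0.71. Of the genes named for these pathways, leaving Ppargc1a aside, all except Fmo5 lost their averaged call with the 3' to 5' covariate, and none without any single array.

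The interaction asks whether the genotype effect changed between 8 and 16 weeks. Hsd3b2 (101659_at), a steroid dehydrogenase abundant in the mouse kidney, was at 24520 and 21180 in db/m kidneys of 8 and 16 weeks and at 19320 and 6075 in db/db kidneys, so its genotype effect went from -0.34 to -1.8 (difference -1.46, SE 0.17, adjusted p from limma 0.00865). Plin2 went from -0.36 to 2.62 (difference 2.97, SE 0.42). The laminin chain Lama5 went from -0.68 to 0.83 (1.51) while Lama3 went from -0.54 to -2.15 (-1.6). Dio1, which activates thyroid hormone, went from -1.39 to 0.47 (1.86) and the small GTPase Rras from -0.25 to 1.79 (2.04). With the probe sets 102026_s_at (1.87) and 92869_at (-2.38), which have no single gene symbol, these were all of the 8 that passed, while 1088 had an unadjusted p under 0.05. With limma, 0 passed with the replicate block (990 at an unadjusted p under 0.05) and 0 without the 2 db/m arrays with the highest Acta1 (645).

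Leaving out single arrays moved the count of 8 by over 1.5 times in 9 cases. It was 2 without db/m 8 week replicates 1, 2 or 3, without db/m 16 week replicate 2, without db/db 8 week replicate 3 and without db/db 16 week replicate 2. It was 15 without db/m 16 week replicate 3, 16 without db/db 8 week replicate 2 and 763 without db/db 16 week replicate 1, the array that lay apart. It was 1160 with array weights, 52 with a variance trend and robust prior, 43 with a filter at the 65th percentile, 34 with a floor at the 45th percentile and 13 without the filter. No single array ended the call of Hsd3b2. Those of Plin2 (adjusted p 0.0711 to 0.116) and Lama5 (0.0711 to 0.092) ended without each of the 6 arrays that left 2 calls. Those of Dio1 (0.0509 to 0.0928) and Rras (0.0601 to 0.132) ended without the same arrays and without db/db 8 week replicate 1, and that of Lama3 (0.0509 to 0.156) without every array other than db/m 16 week replicate 3 and db/db 16 week replicate 1. Over all alternatives the highest adjusted p was 0.0889 for Hsd3b2, 0.146 for Plin2 and Lama5, 0.192 for Dio1, 0.151 for Rras and 0.311 for Lama3.

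Of the gene lists, 4 passed for the interaction, each with adjusted p = 0.0212. The difference of genotype effects averaged -0.54 over 12 markers of the loop of Henle and distal tubule, 0.76 over 16 immediate early genes, -0.39 over 25 genes of heat shock and the unfolded protein response, and 0.42 over 15 clock genes. With an estimated correlation these had adjusted p = 0.72, 0.72, 0.427 and 0.399, the highest of their alternatives, and with fry tubule markers and immediate early genes did not pass (0.202 and 0.515), while proximal tubule markers did (0.0482). Without db/db 16 week replicates 2 and 3 together, immediate early genes turned to lower (0.107, 7.57e-07 to 0.72 over its alternatives). No member passed over all probe sets, and 3 tubule markers fell, 1 heat shock gene rose and 3 fell, and 2 clock genes rose when adjusted over the list alone. The calls ended without single arrays: without db/m 16 week replicate 3 for tubule markers, immediate early genes and heat shock genes (0.101 each), without db/db 16 week replicate 3 for all 4 in the order given (0.0917, 0.196, 0.0935 and 0.0917), without replicate 2 of that group for immediate early genes (0.0561), without its replicate 1 for heat shock genes (0.0565), and without db/m 8 week replicate 2 for heat shock and clock genes (0.0528 each).

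In db/m kidneys, 16 with 8 weeks asks what differed with age, which cannot be told apart from a batch, as none is labelled. Cyp4a14 rose from 1049 to 9433 (101103_at, log2 fold change 3.17, SE 0.43, adjusted p from limma 0.0116, and 0.073 with only the arrays compared, 0.00179 to 0.942 over its alternatives), and Acot1, a cytosolic acyl-CoA thioesterase that like Cyp4a14 is a target of the fatty acid receptor PPAR-alpha, rose by 1.79 (SE 0.18). Sdc4, a heparan sulfate proteoglycan, rose from 1572 to 6220 (1.98, SE 0.23). Genes of fatty acid beta-oxidation and ketogenesis rose as a group: 9 of 29 rose and 1 fell, and 19 and 1 did when adjusted over the list alone (camera, adjusted p = 7.16e-17). This was the 1 list of any comparison that passed with an estimated correlation (adjusted p = 0.0362).

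Other large changes in db/m kidneys with age kept their direction but not their calls when single arrays were left out. They were rises of Zbtb16 (2.44), the immunoglobulin receptor Pigr (1.96) and Fgg (1.96) and falls of the transcription factor Hnf4a (-2.06), the telomere protein Ten1 (-1.82), the disulfide isomerase Pdia6 (-1.73), the ectonucleotidase Nt5e (-1.69) and the glycosyltransferase Gcnt1 (-1.43). Calls ended without db/m 16 week replicate 2 for all 8 (adjusted p 0.059 to 0.168), without its replicate 1 for all except Fgg (0.0567 to 0.173), without db/m 8 week replicate 3 for all except Ten1 (0.0611 to 0.163), without its replicate 2 for all except Ten1 and Pdia6 (0.052 to 0.0804), and without its replicate 1 for Zbtb16, Pigr, Nt5e and Gcnt1 (0.0849 to 0.0916). Those of Pigr and Nt5e also ended without db/db 8 week replicates 1, 2 or 3 (0.0504 to 0.0702), and that of Nt5e without db/db 16 week replicates 2 or 3 (0.0594 and 0.0559). In the fits without single arrays that ended calls the changes were 1.96 to 2.54 for Zbtb16, 1.49 to 2.14 for Pigr, 1.77 to 1.92 for Fgg, -2.14 to -1.8 for Hnf4a, -1.91 to -1.73 for Ten1, -1.72 to -1.5 for Pdia6, -1.85 to -1.34 for Nt5e and -1.55 to -1.32 for Gcnt1. Without the 2 db/m arrays with the highest Acta1 they were 1.3, 1.36, 2.2, -1.44, -1.82, -1.46, -1.14 and -1.11 in this order, and with the 3' to 5' covariate 1.52, 1.07, 2.03, -0.89, -1.9, -1.19, -0.76 and -0.9, where Cyp4a14 was at 2.28 and Sdc4 at 1.39. The highest adjusted p over all alternatives lay between 0.942 and 0.997 for these genes.

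Genes of cholesterol synthesis and uptake were lower in older db/m kidneys: 2 of 14 fell, and 5 did when adjusted over the list alone (camera, adjusted p = 2.64e-06, and adjusted p = 0.0666 with an estimated correlation). Glucocorticoid-responsive genes were higher, with 3 of 18 risen and 8 when adjusted over the list alone (adjusted p = 4.18e-10, and adjusted p = 0.0806 with an estimated correlation). The lists of gluconeogenesis (1 rose, 2 adjusted over the list alone, 0.00978), complement and acute phase (1 rose, 5 adjusted over the list alone, 0.00111), injury (1 rose, 3 adjusted over the list alone, 0.021) and antigen presentation (1 rose when adjusted over the list alone, 1.76e-05) shifted up. With an estimated correlation these had adjusted p = 0.285, 0.349, 0.533 and 0.456, and with fry 0.0521, 0.123, 0.331 and 0.261. Antigen presentation was highest on db/m 16 week replicate 2, with a mean of 1.43 over the 8 week db/m mean against 0.33 and 0.39 on replicates 1 and 3, and without it had adjusted p 0.0316 (1.51e-08 to 0.456 over its alternatives). On that array leukocyte markers were at 0.47 against -0.06 and -0.13, and interferon-response genes at 0.5 against -0.04 and 0.1. The respiratory chain (0.00135) and the renin-angiotensin and vasoactive systems (0.00978, 1 fell when adjusted over the list alone) shifted down, each with adjusted p = 0.283 with an estimated correlation.

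A further 6 lists passed in db/m kidneys with calls that ended without single arrays. Lower were the citric acid cycle (adjusted p = 0.0382), markers of the loop of Henle and distal tubule (0.00834) and the cell cycle (0.0183, 1 fell when adjusted over the list alone), with adjusted p = 0.501, 0.456 and 0.161 with an estimated correlation. Higher were chemokines (0.0468), skeletal muscle (0.0329, 1 rose when adjusted over the list alone) and immediate early genes (0.0329), with adjusted p = 0.465, 0.324 and 0.564 with an estimated correlation. Without db/m 8 week replicates 1 and 2 and db/m 16 week replicates 1 and 2 the citric acid cycle had 0.0521, 0.0606, 0.0986 and 0.147. The cell cycle had 0.0961 without db/m 8 week replicate 2 and 0.0504 without db/m 16 week replicate 2, and tubule markers 0.0612 without db/m 16 week replicate 1. Skeletal muscle had 0.0921 without db/m 8 week replicate 2, 0.0688 and 0.215 without db/m 16 week replicates 1 and 2, and 0.0507 without db/db 16 week replicate 1. Immediate early genes had 0.0617 without db/m 8 week replicate 3 and 0.065 without db/m 16 week replicate 1. Chemokines had 0.096 and 0.192 without db/m 8 week replicates 1 and 3, 0.137 and 0.0504 without db/m 16 week replicates 2 and 3, 0.0535 without db/db 8 week replicate 3 and 0.0526 without db/db 16 week replicate 2. Over all alternatives adjusted p reached 0.869, 0.921, 0.161, 0.465, 0.921 and 0.564 for the 6 lists in the order in which they are introduced. With fry these were 0.205, 0.205, 0.0255, 0.274, 0.12 and 0.457.

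In db/m kidneys 61 probe sets passed with age, 33 higher and 28 lower, and groups were separated for 1688, or 24.3%, where chance gives 10%. The count was 21, 8 and 6 without db/m 8 week replicates 1, 2 and 3, 10, 7 and 102 without db/m 16 week replicates 1, 2 and 3, 34, 34 and 33 without db/db 8 week replicates 1, 2 and 3, and 107 without db/db 16 week replicate 1. It was 263 with array weights, 104 with a variance trend and robust prior, 96 with a floor at the 45th percentile, 94 without db/db 16 week replicates 2 and 3, 28 with the replicate block and 23 with the db/m arrays alone. With limma, 0 passed without the 2 db/m arrays with the highest Acta1 (354 at an unadjusted p under 0.05) and 0 with the 3' to 5' covariate (334), so no gene named for this comparison kept its call there. The actin 3' to 5' ratio was 1.74 (SD 0.356) on the 3 arrays of 8 weeks and 2.5 (SD 0.413) on those of 16 weeks.

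In db/db kidneys, 16 with 8 weeks asks what changed with age, where the course of the disease, ordinary ageing and an unlabelled batch cannot be told apart. Plin2 rose from 2948 to 36870 (log2 fold change 3.64, SE 0.3, adjusted p from limma 0.000177), and Pdk4, the kinase that shuts pyruvate out of the citric acid cycle, from 827 to 18150 (102049_at, 4.46, SE 0.63, adjusted p from limma 0.00253). Of 29 genes of fatty acid beta-oxidation and ketogenesis 17 rose, and 21 did when adjusted over the list alone (camera, adjusted p = 1.87e-11, and adjusted p = 0.058 with an estimated correlation). Among them Angptl4, an inhibitor of lipoprotein lipase, rose by 2.52 (SE 0.36) and Acot1 by 1.31 (SE 0.18). The phosphatidate phosphatase Lpin1, of triglyceride synthesis, rose by 1.89. The beta-oxidation list rose with age in db/m kidneys too, and it did not pass for the interaction. Over the 8 week db/m mean it stood at 0.88, 0.69 and 0.74 on the db/m 16 week arrays. On db/db arrays it was at 0.33, 0.33 and 0.19 at 8 weeks and 1.1, 1.04 and 1.17 at 16 weeks.

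Other large rises with age in db/db kidneys were those of Cdkn1a (2.93), the adaptor Sorbs3 (2.72) and Ptpn22 (2.65). The largest falls were those of Ptger3, a prostaglandin E receptor (-2.64, SE 0.36), the tetraspanin-like Tm4sf5 (-2.43), Fam151a (-2.41), the sialidase Neu1 (-2.26) and Cyp27b1 (-2.65, SE 0.7). The call of Cyp27b1 ended without db/db 8 week replicates 2 and 3 (adjusted p 0.0883 and 0.0897) and db/db 16 week replicates 2 and 3 (0.0897 and 0.104), with a range of 0.0027 to 0.426 over all alternatives. Lama5 rose by 1.65 and Lama3 fell by 1.45.

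Markers of the loop of Henle and distal tubule fell as a group in db/db kidneys: 7 of 12 fell, and 10 did when adjusted over the list alone (camera, adjusted p = 3.66e-05, and adjusted p = 0.298 with an estimated correlation). Ppp1r1a, a phosphatase inhibitor, fell by 1.35 (SE 0.17) and Calb1 by 1.22 (SE 0.23). Of 25 genes of proximal tubule transport 8 fell and 1 rose, and 11 and 1 did when adjusted over the list alone (adjusted p = 0.0462, and adjusted p = 0.484 with an estimated correlation), with Slc15a2 at -0.81. That call ended without db/m 8 week replicate 1 (0.0502), db/m 16 week replicates 1 and 2 (0.0515 and 0.0563), db/db 8 week replicate 2 (0.0754), db/db 16 week replicates 2 and 3 (0.0705 and 0.115) and with the replicate block (0.0535), with a range of 0.0136 to 0.484.

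Clock genes rose in 6 of 15 cases, also when adjusted over the list alone (adjusted p = 0.000138, and adjusted p = 0.058 with an estimated correlation), with Per1 and Rora at 1.35 and Wee1 at 1.33. Glucocorticoid-responsive genes rose in 10 of 18 cases, and 10 rose and 1 fell when adjusted over the list alone (adjusted p = 2.74e-07, and adjusted p = 0.185 with an estimated correlation), with Zbtb16 at 2.63. Immediate early genes rose in 4 of 16 cases, 9 adjusted over the list alone (adjusted p = 2.82e-05), and injury genes in 5 of 22, 6 adjusted over the list alone (0.000135), with adjusted p = 0.371 and 0.41 with an estimated correlation. Without db/db 16 week replicates 2 and 3 both had 0.861, the highest of their alternatives, and with fry injury genes had 0.0515.

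Another 5 lists passed with age in db/db kidneys, with calls that ended without single arrays. Respiratory chain genes fell in 6 of 53 cases, 5 adjusted over the list alone (adjusted p = 0.00537, 0.298 with an estimated correlation, 0.434 on values as deposited, 0.0982 without db/db 16 week replicate 1). Cholesterol genes fell in 3 of 14 cases, 4 adjusted over the list alone (adjusted p = 0.0306, 0.298 with an estimated correlation, 0.0754 without db/db 8 week replicate 2, 0.0737 without db/db 16 week replicate 1), with Cyp51 and Fdps both at -1.15. TGF-beta and BMP genes rose in 4 of 18 cases, 6 adjusted over the list alone (adjusted p = 0.0398, 0.298 with an estimated correlation, 0.115 without db/db 8 week replicate 2, 0.0705 without db/db 16 week replicate 2). Complement and acute phase genes rose in 2 and fell in 1 of 16 cases, 3 and 1 adjusted over the list alone (adjusted p = 0.0306, 0.511 with an estimated correlation, 0.0754 without db/db 8 week replicate 2, 0.0705 and 0.281 without db/db 16 week replicates 2 and 3), with Fgg at 2.04. Antigen presentation genes rose in 2 of 17 cases, 3 adjusted over the list alone (adjusted p = 0.0126, 0.663 with an estimated correlation, 0.444 without db/db 16 week replicate 3). Their mean over the 8 week db/m mean was -0.26, 0.24 and 1.1 on db/db 16 week replicates 1, 2 and 3, where leukocyte markers were at -0.66, 0.09 and 0.75. Without replicates 2 and 3 together complement and antigen presentation turned to lower (0.554 and 0.628, with ranges of 0.00169 to 0.554 and 0.00068 to 0.663). Over all alternatives adjusted p reached 0.434, 0.298, 0.298, 0.554 and 0.663 for these 5, and with fry complement and antigen presentation had 0.125 and 0.318. Fry alone called collecting duct markers (0.00105), amino acid and urea metabolism (0.00431), proximal tubule markers and heat shock (0.00541 each) and the renin-angiotensin system (0.0311), all lower.

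In db/db kidneys 981 probe sets passed with age, 474 higher and 507 lower (409 and 527 on values as deposited, 447 and 294 with a common median), and groups were separated for 1996, or 28.7%, where chance gives 10%. Between the genotypes 27 probe sets passed with age in both, all with the same sign, and the effects correlated at r = 0.352 across probe sets. The count was 622, 489 and 335 without db/db 8 week replicates 1, 2 and 3, 1929, 401 and 475 without db/db 16 week replicates 1, 2 and 3, 152 without the last 2 of these together, 115 with the db/db arrays alone, 2564 with array weights and 319 with the 3' to 5' covariate. Without db/db 16 week replicates 2 and 3 together the calls of Plin2, Tm4sf5, Fam151a, Neu1, Lama5, Lama3, Lpin1, Ppp1r1a and Fgg held among the genes named for this comparison.

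**Figure D4:**
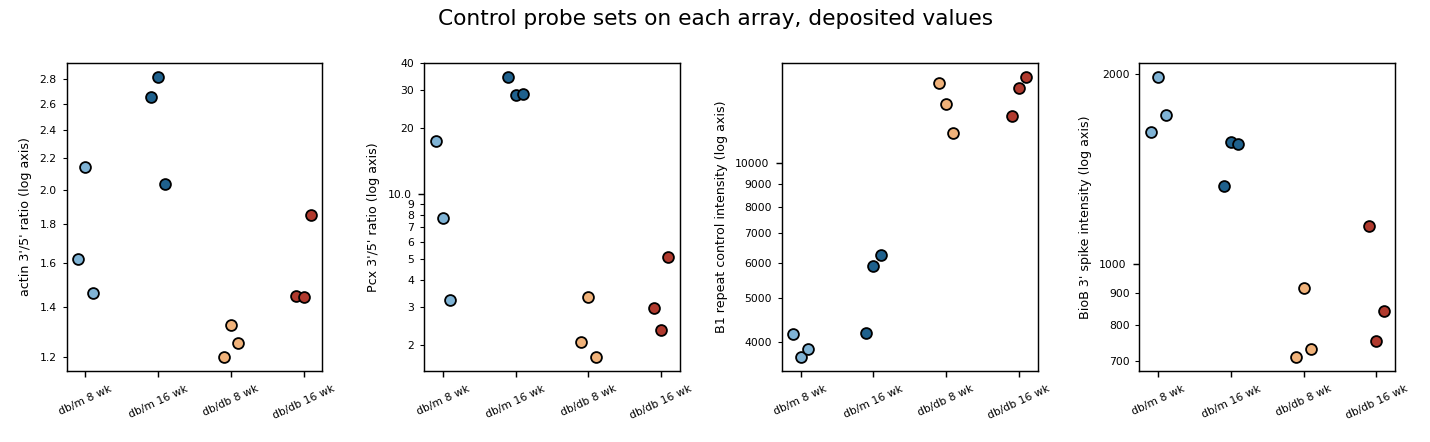
Control probe sets on each array as deposited, on log axes: the 3' to 5' ratios of actin and pyruvate carboxylase, the B1 repeat control and the BioB spike, with 3 arrays per group. The B1 control is higher and BioB lower on every db/db array than on any db/m array, with geometric means of 13810 and 4575 for B1 and 838.5 and 1616 for BioB.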

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

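The splits of the samples were planned before the data were examined, and the tests of 3' bias, scaling, batches, swapped or wrong labels, RNA quality, leukocytes, proximal tubule share, sex and the control probe sets were chosen after the result was seen.

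The genotype effect differed between 8 and 16 weeks by the interaction test for 6 genes and 2 probe sets without a single symbol: the steroid dehydrogenase Hsd3b2 (-1.46), the laminin chains Lama3 (-1.6) and Lama5 (1.51), the lipid droplet protein Plin2 (2.97), the deiodinase Dio1 (1.86), the GTPase Rras (2.04), 102026_s_at (1.87) and 92869_at (-2.38). Mean differences of 4 lists passed as well: loop of Henle and distal tubule (-0.54), immediate early genes (0.76), heat shock and unfolded protein response (-0.39) and circadian clock (0.42). With an estimated correlation none did (adjusted p 0.72, 0.72, 0.427 and 0.399 in this order), and without db/db 16 week replicates 2 and 3 immediate early genes turned to lower (0.107, 7.57e-07 to 0.72 over the list's alternatives). Of 100 splits drawn within the design, 5, the real one included, gave at least its 8 probe sets, so chance is not excluded for this count. With limma, 0 probe sets passed with the replicate block (990 at an unadjusted p under 0.05). The highest other gave 3140: it exchanged the genotype labels at 1 age, which turns the averaged genotype effect into the interaction and points to the genotype structure of the samples.

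Control probe sets, which took part in the normalisation but not in the comparisons, differed between db/db and db/m arrays. As ratios of db/db over db/m geometric means (6 arrays each), the B1 repeat control was at 3.02, the 3' part of 18S ribosomal RNA at 1.85, probe sets for the opposite strand at 1.53 and the spiked BioB control at 0.519. Ratios of 3' to 5' signal were at 0.681 for actin, 0.846 for Gapdh and 0.181 for pyruvate carboxylase. The exact permutation p within age was 0.01 for pyruvate carboxylase and 0.005, the smallest that the permutations can give, for the other 6. Adjusted over 11 array measures these were 0.0138 and 0.00786, while the B2 repeat control was at 1.007 (exact p 0.9).

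Many probe sets differed between genotypes at both ages, and Gsta2, Bhmt, Cyp7b1 and Idi1 led the averaged effect. Scaling between arrays is argued against as the whole cause, since at least 85.4% of the averaged calls kept their sign and call on values as deposited and with a common median. So is 3' bias, by the slope of the changes with the 3' to 5' covariate on those without it. That slope was 0.997 (0.846 to 1.063 without single arrays), and the genotype difference of the Gapdh ratio went from -0.241 to -0.052. The part of the standard error that the design sets grew 2.38 times, as the covariate differed between genotypes, which limits what the slope can show. Whether this growth alone ended the calls was not tested. Genotypes labelled in separate batches cannot be told apart from the genotype effect, as BioB was at 0.519 with no overlap between genotypes and no batch is labelled. Among 100 splits 1, the real one, gave as many as its 3140 probe sets (highest other 497), which excludes chance for the averaged effect, and the biological difference between db/db and db/m mice stays open beside a batch.

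The 10 splits of 3 against 3 arrays are too few for a share under 0.05: in each case 1 split, the real one, gave as many. The real counts and the highest others were 1324 and 0 at 8 weeks, 2357 and 1 at 16 weeks, 61 and 1 for age in db/m kidneys, and 981 and 6 for age in db/db kidneys.

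Transcripts of injury and immediate early response, such as Krt20, Cdkn1a and Junb, were far higher on db/db 16 week replicates 2 and 3 than on replicate 1. An exchange of replicate 1 with a db/db 8 week array is argued against: no 8 week array was closer to replicates 2 and 3 than to its own group (highest difference in mean correlation -0.06). RNA quality cannot be told apart: the 3' to 5' covariate of replicate 1, -0.635, lay between -0.738 and 0.043, but its Gapdh ratio of 0.843 lay below 0.88 and 0.888, and BioB was at 1147 against 755.2 and 841.9. Replicate 1 correlated at 0.942 with the db/db 8 week arrays and at 0.909 with replicates 2 and 3, but that it was an 8 week kidney is argued against by beta-oxidation genes, which rose with age in db/m kidneys: their mean was 1.1 on replicate 1, 1.04 and 1.17 on replicates 2 and 3, and 0.19 to 0.33 on the 8 week arrays. More leukocytes in replicates 2 and 3 cannot be told apart from induction in kidney cells: the median of 17 markers was 1.12 higher, with quartiles of 0.42 and 1.63, and kidneys hold leukocytes of their own. A candidate biological explanation is that the disease had gone further in 2 of the 3 animals, which was not tested.

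Androgen-responsive and sex-dimorphic genes, led by Cyp7b1, Odc1 and Adh1, were lower in db/db kidneys. With an estimated correlation the list did not pass (adjusted p 0.682 at 8 weeks, 0.466 at 16 weeks and 0.483 averaged). For the averaged effect, a lower share of proximal tubule is argued against as the whole cause. The median of 16 proximal markers outside the list was -0.15 (quartiles -0.35 and 0.08), against -0.75 over the 15 genes of the list. The test was not made for 16 weeks alone, where a part for such a loss stays open. There the full proximal list stood at -0.27, -0.39 and -0.41 over the 8 week db/m mean on db/db arrays, and at 0.07, 0 and 0.07 on db/m arrays. Females among the db/db animals cannot be told apart by Xist, which was above the floor on 0 arrays, because no array is known to come from a female. The Y-linked gene Eif2s3y was at 561 to 1243 on the 12 arrays, and whether its probe set also reads the X-linked copy was not tested. Less androgen in db/db mice is a candidate explanation that was not tested, and no hormone value was used. The panel gene Kap, named for its control by androgen in the kidney, did not pass, at -0.17 at 8 weeks and -0.22 at 16 weeks.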

How the results depend on the processing

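The omission of 2 arrays together, the 3' to 5' covariate and the omission of probe sets prone to cross-hybridise were chosen after the result was seen, and the other alternatives were planned. Over 27 alternatives, gene results had the same direction and side of the threshold 9175 times, became weaker 1491 times, stronger 18 times and reversed 49 times. Of 386 called gene results 37 were the same in all alternatives. List results were the same 3940 times, weaker 200, stronger 71 and reversed 7 times, and 248 of 3098 without a call in either had another sign. The cause was not tested except where named.

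With a common median 2166 probe sets passed at 8 weeks, 409 higher and 1757 lower, and 1105 of the 1324 were shared, and values as deposited gave 1691 (1075 and 616). Array weights gave 2355, 3745, 1160, 263 and 2564 for 8 weeks, 16 weeks, the interaction and age in db/m and db/db kidneys. With the covariate, which enlarged the part of the standard errors set by the design, 131, 2, 25, 1, 0 and 319 passed for 8 weeks, 16 weeks, their average, the interaction and age in db/m and db/db kidneys. Of the 131, 124 were shared with the 1324. For the 0 limma had 334 at an unadjusted p under 0.05.

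With only the arrays compared, fewer arrays set the spread: 1318 passed at 16 weeks, 23 for age in db/m and 115 in db/db kidneys. Without db/db 16 week replicates 2 and 3, which leaves 1 array in that group, 809 passed at 16 weeks (671 shared), 1 for the interaction, 94 for age in db/m and 152 in db/db kidneys. Without the 2 db/m 16 week arrays with the highest Acta1 these were 444 at 16 weeks (427 shared), 2033 for the average, and by limma 0 for the interaction (645 unadjusted) and 0 for age in db/m kidneys (354 unadjusted).

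The interaction count of 8 became 34 with a floor at the 45th percentile, 13 without the filter, 43 with a filter at the 65th percentile, 52 with a variance trend and robust prior, and 0 with the replicate block (990 unadjusted by limma). The 61 for age in db/m kidneys became 96 with that floor, 104 with the trend and 28 with the block. Leaving out each array in turn gave 659 to 1857 at 8 weeks, 1451 to 3054 at 16 weeks, 2585 to 3671 for the average, 2 to 763 for the interaction, 6 to 107 for age in db/m and 335 to 1929 in db/db kidneys. The lowest were without db/db 8 week replicate 3, db/db 16 week replicate 2 and db/db 8 week replicate 1. For the interaction they were without any of 6 arrays, and for age without each genotype's 8 week replicate 3. Each highest was without db/db 16 week replicate 1.

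Direction reversed for these genes. With the covariate H2-Ea was at 0.14 (average), Scd1 at 0.51, Atp2a1 at 0.05 and Fn1 at 0.53 (16 weeks), and Umod at -0.08, Cpt1a at -0.15, Fn1 at 0.12, Col4a1 at 0.17 and Ccn2 at 0.07 (8 weeks). With array weights Scd1 was at 0.11 and Fn1 at 0.03 (16 weeks). With a common median Uqcrb was at -0.13 (average), Umod at -0.47, Aqp2 at -0.13, G6pc at -0.44 and Cpt1a at -0.43 (8 weeks) and Ccn2 at -0.23 (16 weeks). On values as deposited Umod was at -0.14, G6pc at -0.11 and Cpt1a at -0.1 (8 weeks), and Fasn at 0 and Fn1 at 0.04 (16 weeks). At 16 weeks without db/db replicates 2 and 3, Slc2a2 was at 0.07, Aqp2 at -0.58, G6pc at 0.22 and Fasn at 0.48. Fasn was at 0.19 without the 2 db/m arrays. Lcn2 was at -0.24 by the probe set representing it, but above db/m by the other (588 against 259 to 437.5).

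Leaving out single arrays reversed genes that had no call. Ranges at 8 weeks were -0.07 to 0.06 for Umod, -0.01 to 0.75 for Aqp2, -0.03 to 0.19 for G6pc, -0.07 to 0.18 for Cpt1a, -0.09 to 0.05 for Col4a1 and -0.27 to 0.19 for Ccn2. At 16 weeks they were -0.7 to 0.45 for Scd1, -0.07 to 0.02 for Cpt1a, -0.28 to 0.1 for Fasn, -0.48 to 0.32 for Fn1 and -0.07 to 0.18 for Ccn2.

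Among the alternatives for which the list tests were run again, which do not include the common median, the test's direction reversed for lists without db/db 16 week replicates 2 and 3. Adjusted p there was 0.00624 at 16 weeks, 0.00113 for the interaction and 0.00302 for age in db/db kidneys for leukocytes, 0.0154 for the interaction and 0.554 for age for complement, 0.107 for the interaction for immediate early genes and 0.628 for age for antigen presentation. With a common median the means of 2 lists with a call turned, glutathione at 8 weeks to -0.02 and beta-oxidation in the average to -0.03. An estimated correlation weakened 54 list results and left 1, beta-oxidation with age in db/m kidneys. The replicate block changed 2 list calls: proximal tubule transport with age in db/db kidneys ended (0.0535) and TGF-beta signalling was gained for the average (0.0471).

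Signal over background limits dim transcripts: on each array 0.719 to 2.04% of kept values lay at the floor of 155, where changes are compressed.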

Other observations

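The test of genes near Lepr and the choice of the counts of opposite probe sets were made after the result was seen, and the gene lists were planned.

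Lists of the loop of Henle, collecting duct, podocytes and vessels passed neither with camera nor with fry for the averaged genotype effect. Single markers passed, as did 3140 of all 6954 probe sets. Adjusted p is that of camera. Among 12 genes of the loop of Henle and distal tubule, Calb1, which buffers calcium, rose by 1.13 and Ppp1r1a, a phosphatase inhibitor, fell by 1.14 on the log2 scale (list: 2 rose and 4 fell, 2 and 5 adjusted over the list alone, adjusted p = 0.802). The vasopressin receptor Avpr2 of the collecting duct fell by 0.68 (1 of 10 rose and 2 fell, 0.797). Of 11 podocyte genes 4 rose and 2 fell, 4 and 3 adjusted over the list alone (0.802): Dpysl2 rose by 1.08, while the endopeptidase Mme fell by 0.84 and the transcription factor Tcf21 by 0.86. Of 17 genes of endothelium, mesangium and smooth muscle 3 rose and 6 fell, 3 and 7 adjusted over the list alone (0.799), with endoglin, Eng, at -0.81.

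Transcripts of blood, fat and adrenal gland, which can come with a kidney, differed for single genes. Hemoglobin Hbb-b2 went from 6240 to 18650 at 8 weeks and from 4040 to 10740 at 16 weeks in db/m and db/db kidneys, 1 of 6 erythrocyte genes to rise (adjusted p = 0.39). Leptin, Lep, was at 1160 and 2517 at 8 weeks, and of 12 adipocyte genes 2 rose and 2 fell in the averaged effect (0.634). The mean of the adipocyte genes over the 8 week db/m mean was 0.95 on db/db 8 week replicate 1 and 0.05 and -0.01 on replicates 2 and 3. The adrenal genes Nr5a1, a transcription factor of steroid-making cells, and Cyp21a1, a steroid hydroxylase, rose by 0.74 and 0.79, and 3 of 7 adrenal genes rose and 1 fell (0.298, and 0.0211 with fry). Of the genes named in these 2 paragraphs none kept its averaged call with the 3' to 5' covariate, with adjusted p of 0.0886 for Ppp1r1a and 0.842 for Eng as lowest and highest.

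The db mutation lies in Lepr, and a stretch of chromosome carried along with it could differ between genotypes. Within 10 Mb of Lepr 15 of 40 probe sets, or 37.5%, passed for the averaged effect, against 45.3% elsewhere (Fisher's exact p 0.343), so no excess of calls was found there.

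Probe sets of one gene did not always move together. Of 821 genes with at least 2 kept probe sets, 48 had at least 2 that passed at 8 weeks, with opposite signs in 11, and 139 did at 16 weeks, with opposite signs in 21. At 16 weeks these include Dynll2, at 1.69 on the probe set used for the report and -0.63 on another, and Pdia6, at 1 and -1.14 in the same way.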
